A study of Escherichia coli with 12 samples.

How the data were processed

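RNA was sequenced from 12 samples of an extraintestinal pathogenic Escherichia coli isolate grown in cation-adjusted Mueller-Hinton broth, in 4 groups of 3. Per the labels, the groups were untreated, an extract of cranberry pomace below its inhibitory concentration, ceftriaxone below its inhibitory concentration, and both agents. Doses and exposure times were not given in the sources used here. Per the labels' protocols, RNA was isolated with the PureLink RNA Mini Kit and libraries were made with the TruSeq Stranded mRNA kit. The labels number the replicates 1, 3 and 4 in the untreated group and 1, 3 and 5 in the other groups.

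The deposited file is a table of 4961 genes by 12 libraries that holds expected counts per gene, not normalized by the authors as far as the values show. Per the submitters' processing notes, STAR 2.6.1d and Salmon 1.4.0 were among the tools used, with no role stated for either. The genome and the annotation were not given in the sources used here. Of all deposited estimated counts, 97.6% lay within 0.01 of a whole number, and all were rounded to whole numbers before the tests, which changed no library total by more than 1.7e-05%. The table pairs 3807 of the gene identifiers with a symbol and leaves 1154 without one. For 510 genes the symbol carries a copy number (_1, _2 and so on). The counting can split reads between such copies, so their values are uncertain. All 12 columns were matched to samples by name, and every library was used.

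Library totals ran from 5.99 to 15.46 M counts. At the smallest total, 3 counts correspond to 0.501 counts per M counts (CPM), and such limits cover counting error only. Every pair of replicates differed by more than sampling noise, so each library was counted as its own sample. The labels do not say whether replicates came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.

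The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the rounded counts of all 12 libraries in 1 fit with a mean per group. Counts were scaled by TMM, and filterByExpr kept 4707 genes. Log2 fold changes used a prior count of 0.125, and CPM values are relative to the TMM-scaled library total. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. The 6 comparisons were extract against untreated, ceftriaxone against untreated, the combination against untreated, against ceftriaxone and against the extract, and the interaction. The interaction is the effect of ceftriaxone with the extract minus its effect without the extract, on the log2 scale. Across genes, the median biological coefficient of variation was 19.4%.

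Before the data were examined, 33 gene lists were fixed, and each tested list appears with its result in the results section. For 1 of them, the list of stable RNAs, no member was matched, and it was not analysed here. The other 32 were tested with camera (limma 3.58.1) on voom values with the inter-gene correlation preset at 0.01, adjusted over the lists of a comparison. Beside each call in the main fit stands the adjusted p from camera with the correlation estimated from the data. For calls in the alternative fits it was not computed. Another test, fry, asks whether the members of a list move on balance in 1 direction. List members were matched by plain symbol. Numbered copies stayed out. A symbol of the table was read as an older name of a K-12 gene, from RefSeq's gene table of assembly ASM584v2, only where it names 1 such gene and stands in no list. This restriction was added after a first matching had placed genes in wrong lists.

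The rule for naming genes was also fixed before the data were examined. It takes genes that carry a symbol, with an adjusted p under 0.05, a mean CPM of 10 or more and no overlap between the replicates of both groups. Of these it names the 8 largest rises and the 8 largest falls in each comparison with the untreated group, and the 5 and 5 in each of the other comparisons, without the overlap criterion for the interaction. At most 2 genes in a direction may share the first 3 letters of their symbol. The rule adds up to 4 members of each list called by camera, up to 3 members of other lists described, and a panel of genes tied to β-lactams and stress, whatever their result. Genes outside the rule are said to be chosen after their values were seen.

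The scripts were tested on simulated counts drawn from the mean levels, library sizes and dispersion trend of these libraries. Each gene was drawn independently around a single mean over all 12 libraries. The wide extract effect, co-varying genes and outlying libraries of the real data were absent, so recovery there can differ. With 2-fold changes in about 200 genes, edgeR recovered 71.4% of them in the comparison of extract and untreated, 70% for ceftriaxone and untreated, 65.7% for combination and extract and 23.5% for the interaction. Of 1.5-fold changes it recovered 3.5% for extract and untreated, 6% for ceftriaxone and untreated, 3.5% for combination and extract and 0.5% for the interaction. Of 4-fold changes, 99% were recovered for ceftriaxone and untreated and 92.4% for the interaction.

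Alternatives fixed before the data were examined were DESeq2 size factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a mean of 50 or more counts, the replicate number as a block, glmTreat against a 1.5-fold change, only the 6 libraries compared, a prior count of 2 and leaving out each library. Others were chosen after seeing the data: a robust dispersion fit, limma-voom with library weights, leaving out both untreated 1 and cranberry 1, thinning every library to 5.99 M, and numbered copies counted as list members. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.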

Results

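Transcript levels were measured by RNA sequencing in an extraintestinal pathogenic Escherichia coli isolate, a strain of the kind that infects sites outside the gut. The samples formed 4 groups of 3: untreated, exposed to an extract of cranberry pomace (the press residue of the fruit), exposed to ceftriaxone (a cephalosporin that binds penicillin-binding proteins), and exposed to both. Both agents were used below the concentrations that stop growth. Library totals were 13.67, 12.95 and 12.2 M counts for untreated replicates 1, 3 and 4. They were 5.99, 8.97 and 9.75 M for extract replicates 1, 3 and 5, 15.46, 13.85 and 13.73 M for ceftriaxone, and 11.32, 10.56 and 9.86 M for the combination. Of the 4961 genes, 4707 were tested. Values per gene are counts per M counts (CPM, mean ± SD, n = 3), and fold changes are log2 ± SE.

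The extract was the main source of difference between libraries. The first principal component held 83.3% of the variance and placed the 6 libraries without the extract between -64.8 and -45.2, and the 6 with it between 41.7 and 60.3. Within the untreated group, replicate 1 lay farthest from the others, and within the extract group replicate 1 did, at root mean square log2 distances of 0.55 to 0.62 and 0.69 to 0.72. Within the combination group replicate 5 did, at 0.57 to 0.67.

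**Figure D1:**
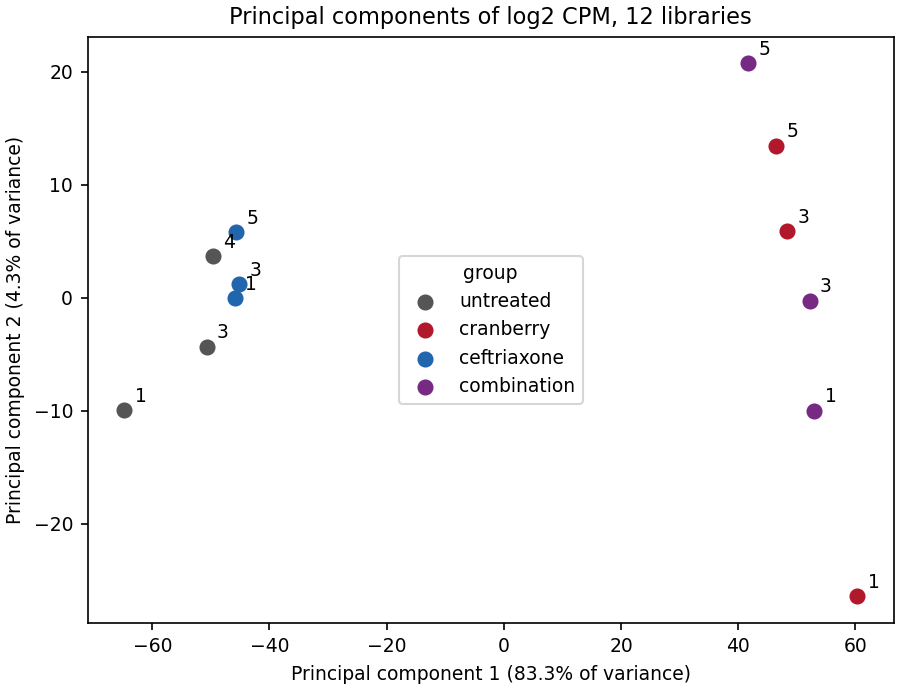
Principal components of log2 CPM for the 12 libraries, coloured by group and marked with the replicate number; the axes are component scores. Component 1 holds 83.3% of the variance and separates the libraries with and without the extract, while ceftriaxone and untreated libraries lie close together.

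The comparison of the extract with no treatment asked what the extract alone did to the transcriptome. Camera called 11 of 32 gene lists, 6 higher and 5 lower, led by a lower list for the tricarboxylic acid (TCA) cycle and a higher list for cysteine and methionine synthesis. None of these calls held with an estimated correlation (adjusted p 0.227 to 0.701). Among genes that met the naming rule, the largest rise was in yhjX (identifier Ecoli_2532_04006), which encodes a transporter of the major facilitator family. Its level went from 14.75 ± 1.57 to 51760 ± 4180 CPM, a log2 fold change of 11.78 ± 0.29. The largest fall among such genes was in ssnA (Ecoli_2532_00582), a putative aminohydrolase, from 3638 ± 1160 to 7.02 ± 1.08 CPM (log2 -9.02 ± 0.35).

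Among the other large rises, the acid shock gene asr went from 2.54 ± 0.15 to 912 ± 176 CPM (log2 8.48). The sulfate and thiosulfate transporter genes cysU and cysW rose by 7.44 and 7.39 on the log2 scale. The stress-induced gene yhcN rose by 7.21, the glutaredoxin gene grxA by 6.56, dmlA (D-malate dehydrogenase) by 6.26 and aaeX, next to the aromatic acid efflux genes, by 6.22. The large falls included ygeY (a putative peptidase), from 12810 ± 547 to 39.1 ± 5.18 CPM (log2 -8.35). The putative oxidoreductase genes ygfM and ygfK changed by -8.27 and -8.26, ygeX (diaminopropionate ammonia-lyase) by -8.21 and xdhD (a predicted xanthine oxidase subunit) by -8.13. The galactose transporter gene mglA changed by -8.18 and sdhC, a membrane subunit of succinate dehydrogenase, by -7.86. By the naming rule, the replicates of both groups did not overlap for any of these 16 genes, and edgeR's adjusted p was at most 4.65e-07.

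Among the lists called lower were those for the TCA cycle, sugar uptake, ribosomal proteins and fatty acids. Of 48 members of the list for the TCA cycle and aerobic respiration, 45 fell, 1 rose and 2 did not pass, the same counts when adjusted over the list alone. The median was -1.52 (camera, adjusted p = 7e-11; adjusted p = 0.485 with an estimated correlation). Succinate dehydrogenase genes led, with sdhA at -6.40 (1726 to 20.4 CPM) and sdhB at -5.85, and malate dehydrogenase (mdh) fell by 3.65. The member that rose was ndh, an NADH dehydrogenase, by 1.70 (edgeR, adjusted p = 5.02e-06), named after its value was seen. In the list for sugar uptake and catabolism, 32 of 54 members fell and 12 rose (14 rose adjusted over the list alone), with a median of -0.97 (camera, adjusted p = 0.00921; adjusted p = 0.485 with an estimated correlation). The galactose-binding protein gene mglB fell by 7.37 and the arabinose transporter genes araF and araG by 4.55 and 3.45. Of 53 ribosomal protein genes, 33 fell, 5 rose and 15 did not pass, with the same counts adjusted over the list alone and a median of -0.84 (camera, adjusted p = 0.00111; adjusted p = 0.537 with an estimated correlation). Examples were rplW at -3.84, rplD at -3.25, rplB at -3.16 and rplC at -2.67. As log2 values relative to gene means, the ribosomal list median was 0.83 in untreated 1, against 0.41 and 0.31 in untreated 3 and 4. It was -0.73 in extract 1, against -0.06 and -0.29 in extract 3 and 5, so replicate 1 of each group widened the difference. Of 20 genes of fatty acid synthesis and degradation, 12 fell and 2 rose, also when adjusted over the list alone (median -0.83; camera, adjusted p = 0.0222; adjusted p = 0.537 with an estimated correlation). Among them were fadL, a fatty acid transporter of the outer membrane (-2.71), accC (-1.56) and fabA (-1.44). Each member named here passed edgeR's test at an adjusted p of at most 8.06e-06.

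Among the lists called higher were those for cysteine and methionine synthesis, heat shock, SOS and oxidative stress. In the list for cysteine and methionine synthesis, 22 of 39 members rose and 3 fell, also when adjusted over the list alone (median 1.03; camera, adjusted p = 6.97e-06; adjusted p = 0.389 with an estimated correlation). Here cysP (sulfate binding) rose by 6.30 and cysI (sulfite reductase) by 6.33. Of 21 heat shock chaperone and protease genes, 17 rose and none fell (18 rose adjusted over the list alone), with a median of 1.32 (camera, adjusted p = 5.73e-05; adjusted p = 0.389 with an estimated correlation). The heat shock sigma factor gene rpoH rose by 2.38, the protease gene hslV by 2.06 and the chaperone gene dnaJ by 1.92. In the SOS list for the response to DNA damage, 14 of 22 rose and 2 fell, with the same counts adjusted over the list alone (median 0.92; camera, adjusted p = 0.000883; adjusted p = 0.227 with an estimated correlation). Members were umuD of error-prone repair (2.56), the nuclease gene cho (2.17) and polB, a repair polymerase (1.73). Of 29 genes for oxidative and electrophile stress, 15 rose and 6 fell (15 and 7 adjusted over the list alone; median 0.59; camera, adjusted p = 0.0244; adjusted p = 0.389 with an estimated correlation). They included the quinone reductase genes ytfG, an older name of qorB (4.79), azoR (3.24) and mdaB (2.45), and the redox-sensing regulator gene soxR (3.84). Each named member passed edgeR's test at an adjusted p of at most 4.62e-06.

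Of the 4 lists on metals, those for iron uptake and for copper and zinc efflux were called higher, and those for iron storage and for zinc and manganese uptake were not called. Of 35 iron uptake genes, 15 rose, 2 fell and 18 did not pass, and the counts were the same adjusted over the list alone (median 0.77; camera, adjusted p = 0.0112; adjusted p = 0.389 with an estimated correlation). The ferrous iron transporter gene feoB rose by 1.37, tonB by 1.74 and fhuF, for ferrioxamine use, by 2.33. Of 10 copper and zinc efflux genes, 8 rose and 1 fell, also when adjusted over the list alone (median 1.04; camera, adjusted p = 0.0112; adjusted p = 0.227 with an estimated correlation). The copper pump gene copA rose from 588 ± 56 to 3044 ± 541 CPM (2.37), and the zinc genes zntR and zntA rose by 1.81 and 1.07 (edgeR, adjusted p at most 0.000218 for these 6 genes).

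In the list for flagella and chemotaxis, 27 of 47 members fell, 3 rose and 17 did not pass, the same counts when adjusted over the list alone. The median was -1.25 (camera, adjusted p = 0.0403; adjusted p = 0.701 with an estimated correlation). The master regulator genes flhC and flhD fell by 4.06 and 3.98, and the flagellin gene fliC by 2.42 (edgeR, adjusted p at most 3.58e-06). Untreated replicate 1 held high flagellar transcripts, and without it the list median was -0.50 (camera, adjusted p = 0.124). The list's call was also lost without extract replicate 3 (-1.19, adjusted p = 0.0504) and without extract replicate 5 (-1.19, adjusted p = 0.121).

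Several genes tied to entry, export and targets of β-lactams changed. The porin genes ompC and ompF, whose products let small molecules cross the outer membrane, fell from 16530 ± 5250 to 1327 ± 264 CPM (-3.64 ± 0.33) and from 234 ± 77.3 to 19.97 ± 0.77 CPM (-3.55 ± 0.27). The regulator genes soxS and marA rose by 3.996 and 1.887. Of the penicillin-binding protein genes, mrcA fell by 1.22 and mrcB by 0.45, while ftsI changed by 0.28 (edgeR, adjusted p = 0.127). The β-lactamase gene copy ampC_2 fell from 1154 to 560 CPM (-1.04, edgeR adjusted p = 0.000143). The copy ampC_1 fell by 0.48 (edgeR, adjusted p = 0.0366). Its call was lost without untreated 1 (log2 -0.44, adjusted p = 0.0847), untreated 3 (-0.45, 0.0895), extract 1 (-0.38, 0.0985) or extract 3 (-0.45, 0.0942). Of the efflux pump genes, tolC_1 and tolC_2 fell by 1.18 and 2.97, acrB_1 fell by 0.63 and acrB_2 rose by 0.63, while acrA_1 and acrA_2 changed by -0.27 and 0.37 without passing. The DNA damage genes recA and sulA rose by 0.843 and 0.998. The iron genes fur, fepA and entB changed by -0.45, 0.11 and 0.68 with edgeR adjusted p of 0.229, 0.697 and 0.0845.

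The other 21 lists were not called by camera, though members of each passed edgeR's test, in both directions except for capsule and virulence (0 rose and 4 fell). Among envelope lists, 2 of 11 outer membrane porin genes rose and 7 fell (camera, adjusted p = 0.162), with ompW at -4.76. Of 35 genes for fimbriae, curli and biofilm matrix, 6 rose and 18 fell (0.172), among them pgaA, for export of a biofilm polysaccharide, at -4.15. Counts of rises and falls were 8 and 13 of 33 for lipopolysaccharide and PhoPQ-PmrAB (0.414), 9 and 11 of 34 for peptidoglycan synthesis and penicillin-binding proteins (0.932), and 7 and 9 of 30 for peptidoglycan remodelling and recycling (0.803). They were 14 and 7 of 29 for multidrug efflux and its regulators (0.151), 0 and 4 of 5 for capsule and virulence (0.172), 1 and 6 of 13 for Cpx envelope stress (0.526), 5 and 8 of 24 for sigma E and phage shock (0.802), and 5 and 4 of 22 for Rcs and colanic acid (0.364).

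Among lists for metabolism and general stress, 4 of 20 acid resistance genes rose, asr included, and 9 fell (camera, adjusted p = 0.266), such as the regulator gene gadW (-3.08). Of 53 genes for anaerobic respiration and fermentation, 13 rose and 25 fell (0.172), with the lactate dehydrogenase gene ldhA at 3.87 and the nitrite reductase gene nrfA at -3.86. Of 19 genes for iron storage and iron-sulfur clusters, 10 rose, such as nfuA (2.93), and 6 fell, such as the ferritin gene ftnA at -3.57 (0.145). Rises and falls were 8 and 11 of 30 for RpoS general stress (0.505), 13 and 10 of 36 for arginine, histidine, tryptophan and branched-chain amino acids (0.526), and 5 and 15 of 31 for purine and pyrimidine synthesis (0.151). They were 7 and 5 of 33 for aromatic acid efflux and catabolism (0.427), 7 and 12 of 29 for galacturonate and hexuronate catabolism (0.414), 8 and 5 of 21 for phosphate starvation (0.526), 5 and 3 of 10 for zinc and manganese uptake (0.414) and 2 and 5 of 12 for plasmid transfer (0.395).

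In total, edgeR called 3026 of 4707 genes between extract and untreated, 1463 higher and 1563 lower, of which 1983 changed by more than 2-fold. Replicates did not overlap for 3170 genes (67.3%, against 10% by chance). Genes share the same libraries and are not independent, so here and below the 10% is an average without a spread. Scaling by library totals alone moved the median log2 change of all genes to -0.12, so small changes are relative to that choice. The test fry called 26 of the 32 lists.

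**Figure D2:**
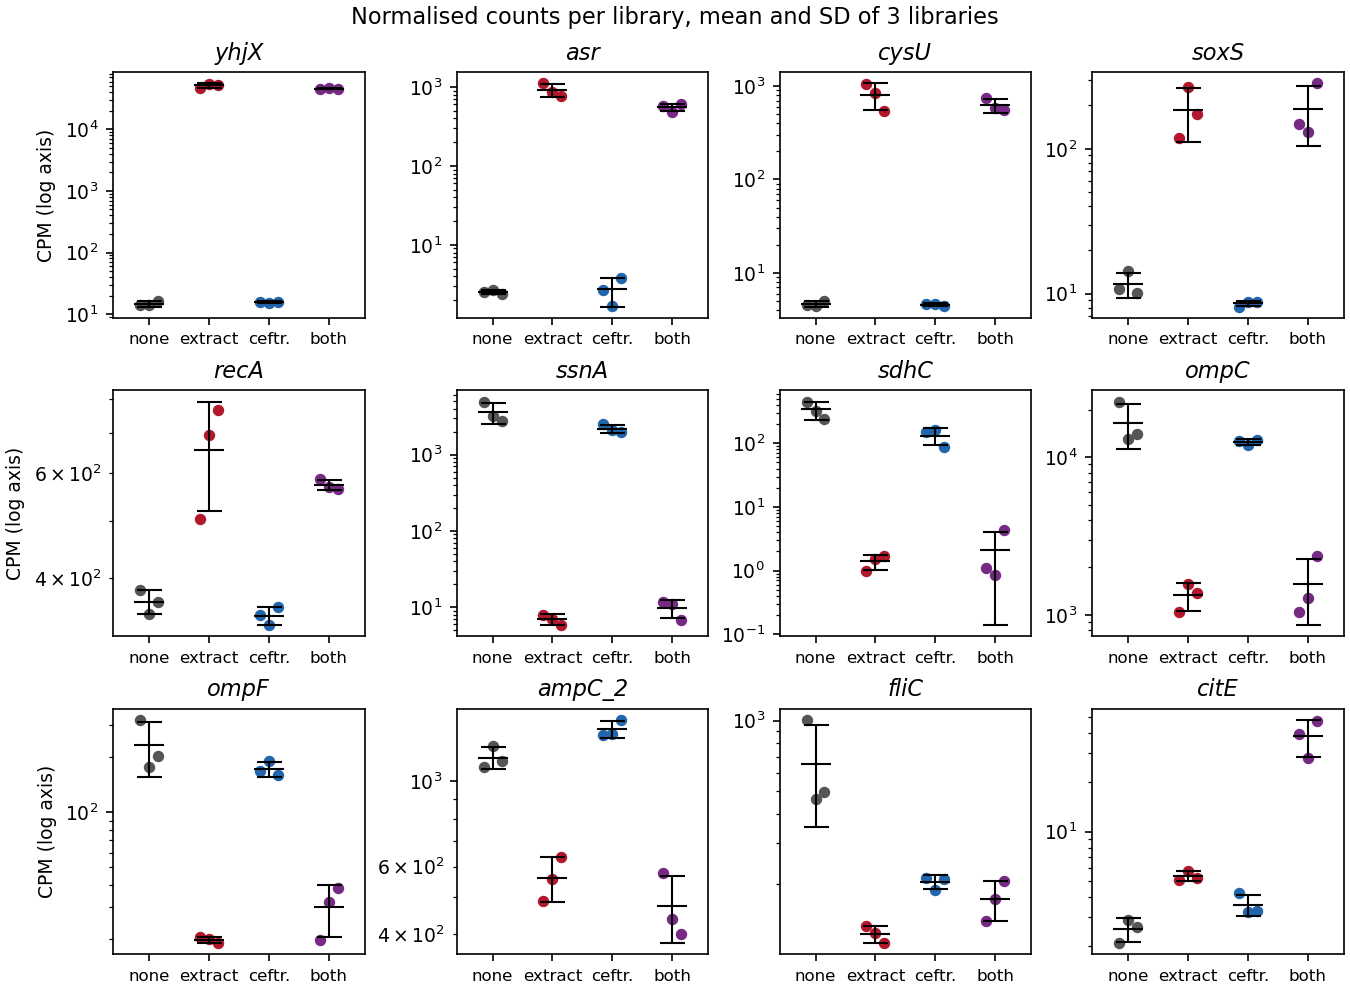
Normalised counts (CPM, log axes that differ between panels) of 12 named genes in each of the 12 libraries: none is untreated, ceftr. is ceftriaxone and both is the combination. Points are libraries and bars the mean and SD of 3. yhjX rose from 14.75 to 51760 CPM with the extract, and citE stood higher in the combination (38.3 CPM) than with the extract alone (5.38 CPM).

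The comparison of ceftriaxone with no treatment asked what the antibiotic alone did at this concentration. edgeR called 2 of 4707 genes, both lower. The flagellin gene fliC (Ecoli_2532_00810) fell from 656 ± 306 to 204 ± 13.9 CPM (log2 -1.68 ± 0.26, adjusted p = 0.0381). The gene ydjK, a putative transporter, fell from 83.9 ± 6.54 to 39.1 ± 4.67 CPM (log2 -1.10 ± 0.17, adjusted p = 0.0381). No gene of the β-lactam and stress panel passed: edgeR's adjusted p ran from 0.345 for acrB_1 to 0.992 for entB. The panel values included 0.24 ± 0.17 for ampC_2, -0.08 ± 0.16 for recA, 0.06 ± 0.16 for sulA, -0.02 ± 0.15 for ftsI and -0.40 ± 0.30 for ompC.

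Camera called 5 lists, none held with an estimated correlation, and fry called 0 of 32. The TCA list had a median of -0.77 (camera, adjusted p = 1.79e-25; adjusted p = 0.571 with an estimated correlation), and no member passed over all genes while 28 were lower when adjusted over the list alone. The cytochrome oxidase genes cyoB and cyoA were at -1.85 and -1.63 and sdhB at -1.46 (edgeR, adjusted p 0.108 to 0.112). The flagellar list had a median of -1.01 (camera, adjusted p = 1.51e-16; adjusted p = 0.571 with an estimated correlation), with 1 member passing over all genes and 26 lower when adjusted over the list alone. Without untreated replicate 1, these medians were -0.34 for the TCA list and -0.27 for the flagellar list, and both camera calls held. The lists for arginine, histidine, tryptophan and branched-chain amino acid synthesis (median -0.26, camera adjusted p = 0.00643) and for fatty acid synthesis and degradation (-0.10, 0.044) were lower, and the heat shock list was higher (0.11, 0.0194). Each had an adjusted p of 0.571 with an estimated correlation. When adjusted over the list alone, 0, 1 and 1 of their members passed, and ibpB, a small heat shock chaperone gene, was at 2.84 (edgeR, adjusted p = 0.207 over all genes). Without untreated 1 their camera calls were lost, at -0.12 (adjusted p = 0.0508), -0.04 (0.0951) and 0.03 (0.304). All 3 were also lost without ceftriaxone 5, at -0.17 (0.101), -0.11 (0.13) and 0.08 (0.101), and the amino acid and fatty acid lists without untreated 3, at -0.23 (0.0583) and -0.11 (0.0583). With library totals alone the fatty acid median was 0.03 and its call was lost (0.0642), while the amino acid and heat shock medians were -0.12 and 0.23. The fatty acid median was -0.16 without untreated 4 and without ceftriaxone 3, and the heat shock median 0.18 without untreated 3.

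At an unadjusted p under 0.05 there were 413 genes, where chance alone would give a share of 0.05 of the 4707 tested. This number was 143 without untreated 1 and 213 without ceftriaxone 5, each of 4726 tested and under that share. Without each of the other libraries compared it ran from 283 (without ceftriaxone 3) to 614 (without untreated 4). DESeq2 called 48 genes, limma-voom 5 and limma-voom with library weights, a test chosen after seeing the data, 251 (45 higher and 206 lower). edgeR called 0 with library totals alone or without the filter. In simulated data without the wide extract effect or an outlying library, edgeR recovered 6% of 1.5-fold and 70% of 2-fold changes in this comparison. The call of fliC was lost without any of the 3 ceftriaxone libraries (log2 -1.69 to -1.61, adjusted p 0.241 to 0.381), and that of ydjK was lost without untreated 1 or 3 or any ceftriaxone library (-1.19 to -1.03, 0.136 to 0.392). The number of genes called by edgeR was 52 without untreated 4, 1 without untreated 1, 1 without untreated 3 and 0 without any ceftriaxone library. For 77.5% of genes the 95% interval of the change lay within 2-fold in either direction, and replicates did not overlap for 1016 genes (21.6%, against 10% by chance). Since genes are not independent, the share without overlap cannot by itself decide on an effect of ceftriaxone. Scaling by library totals alone moved the median of all genes to 0.12.

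The combination was compared with the untreated group to see the joint effect of both agents. edgeR called 2992 genes, 1445 higher and 1547 lower, with 1885 changed by more than 2-fold. Large rises were seen in yhjX (11.61 ± 0.29, to 46160 ± 1270 CPM), asr (7.76), yhcN (7.34), cysW (7.19), cysA of the same sulfate transporter (7.09), grxA (6.32), aaeX (6.03) and dmlA (5.83). Large falls were seen in ssnA (-8.51 ± 0.34), ygeY (-8.19), ygfK (-8.10), ygeX (-8.05), ygfM (-8.04), xdhD (-7.92), mglA (-7.59) and hyuA, a hydrolase gene (-7.59). edgeR's adjusted p was at most 6.25e-07 for these genes.

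Camera called 10 lists in this comparison and fry 25 of 32. The TCA list was called lower (45 of 48 members fell and 1 rose; median -1.51, adjusted p = 3.91e-11; adjusted p = 0.392 with an estimated correlation), as were ribosomal proteins (33 fell and 3 rose of 53; -0.88, 0.000731; 0.539 with an estimated correlation), sugar uptake (33 fell and 13 rose of 54; -0.91, 0.00922; 0.392) and fatty acid genes (12 fell and 2 rose of 20; -0.82, 0.037; 0.539). The cysteine and methionine list was called higher (24 rose and 3 fell of 39; 1.06, 8.42e-07; adjusted p = 0.265 with an estimated correlation), and so were heat shock (17 and 0 of 21; 1.22, 0.000221; 0.392) and SOS (14 and 1 of 22; 0.78, 0.000808; 0.265). Copper and zinc efflux (8 and 1 of 10; 0.77, 0.0268; 0.265 with an estimated correlation), iron uptake (18 and 2 of 35; 0.67, 0.0268; 0.392) and oxidative stress (15 and 5 of 29; 0.63, 0.037; 0.392) were also called higher. Adjusted over the list alone the same numbers rose and fell, except 16 rises for oxidative stress. The fatty acid call was lost without untreated 1 (-0.66, 0.0587) and without combination 5 (-0.73, 0.134), and the iron uptake call without combination 5 (0.57, 0.0561). In the panel, ompC, ompF and ampC_2 fell by 3.40, 2.96 and 1.29, and soxS, marA, recA and sulA rose by 4.01, 2.39, 0.65 and 0.59 (edgeR, adjusted p at most 0.00516).

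Replicates did not overlap for 3179 genes (67.5%, against 10% by chance).

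The comparison of the combination with ceftriaxone alone measured the extract's effect in the presence of the antibiotic. The same named genes led: yhjX rose by 11.52 ± 0.28, asr by 7.66, cysU by 7.10, cysA by 6.93 and yhcN by 6.88. Large falls were again seen in ssnA (-7.77 ± 0.33), ygeY (-7.74), ygeX (-7.50), ygfM (-7.42) and ygfK (-7.29), all with an edgeR adjusted p of at most 4.06e-09. The porin genes ompC and ompF fell by 3.002 and 2.524, mrcA by 0.94 and ampC_2 by 1.53, from 1366 to 473 CPM. The regulator gene soxS rose by 4.46 and recA by 0.73, while fur (-0.52, adjusted p = 0.174) did not pass edgeR's test. The change of ftsI (0.47, edgeR adjusted p = 0.0163) lost its call without ceftriaxone 3 (0.47, adjusted p = 0.0523), ceftriaxone 5 (0.36, 0.102) or combination 3 (0.41, 0.0705).

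Camera called 9 lists and fry 27 of 32. Called higher were cysteine and methionine synthesis (25 of 39 members rose and 2 fell; median 1.03, adjusted p = 2.96e-07; adjusted p = 0.292 with an estimated correlation), heat shock (14 and 0 of 21; 0.77, 0.00112; 0.397 with an estimated correlation) and SOS (13 and 1 of 22; 0.82, 0.00173; 0.292). So were copper and zinc efflux (6 and 1 of 10; 0.63, 0.0356; 0.292), oxidative stress (16 and 4 of 29; 0.68, 0.0356; 0.397) and iron uptake (17 and 2 of 35; 0.53, 0.0393; 0.397), in the same order of values. Called lower were the TCA list (34 of 48 fell and 1 rose; -0.88, 2.96e-07; 0.472 with an estimated correlation), ribosomal proteins (30 and 4 of 53; -0.77, 0.00143; 0.515) and sugar uptake (30 and 11 of 54; -0.66, 0.0124; 0.397). Adjusted over the list alone these numbers were the same, except 31 falls for ribosomal proteins and 12 rises for sugar uptake. The iron uptake call was lost without ceftriaxone 3 (0.50, adjusted p = 0.0658), combination 1 (0.60, 0.0503) or combination 5 (0.49, 0.0999), and the copper and zinc call without combination 1 (0.58, 0.0503). The heat shock median was 1.19 without ceftriaxone 5, and the iron uptake median 0.35 with library totals alone. The flagellar list was not called here: 13 members rose and 5 fell of 47, with a median of 0.02.

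edgeR called 2813 genes, 1391 higher and 1422 lower, with 1668 changed by more than 2-fold and no overlap of replicates for 3292 (69.9%, against 10% by chance). Scaling by library totals alone moved the median of all genes to -0.15 and the share of higher calls from 49.4% to 39.2%. The extract's effects without and with ceftriaxone come from separate libraries. Across genes, which are not independent replicates, they correlated with Pearson's r = 0.949 and Spearman's rho = 0.938. Both comparisons called 2514 genes, 1212 higher and 1302 lower in both, with 0 in opposite directions, against 432.3 and 472.2 expected of independent lists.

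**Figure D3:**
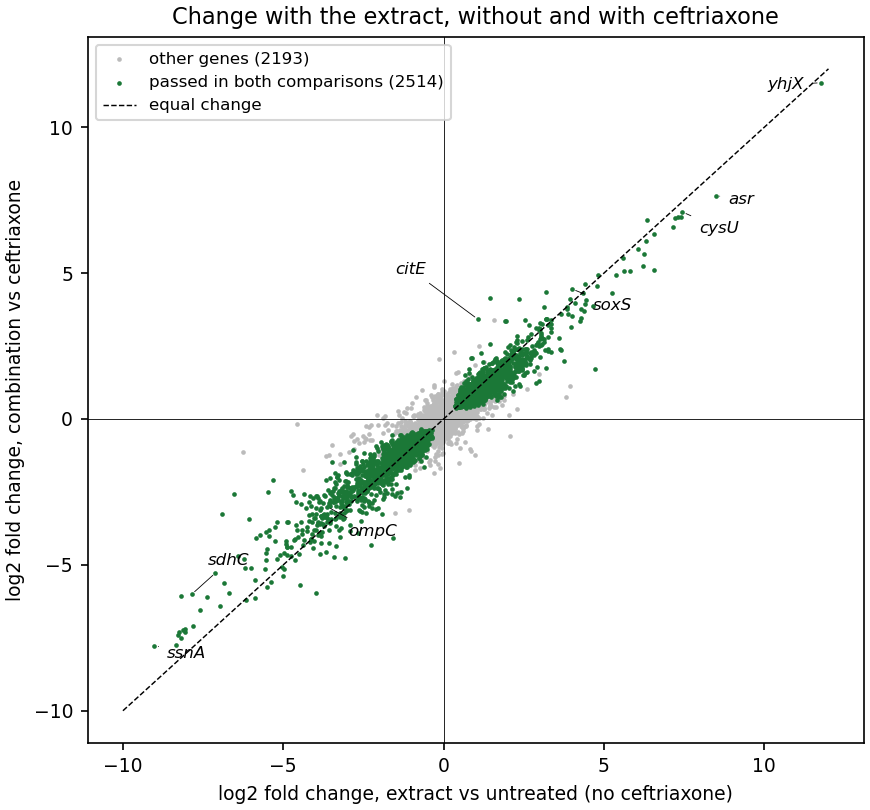
Log2 fold change of each of the 4707 tested genes with the extract against no treatment (x axis) and in the combination against ceftriaxone alone (y axis); green points passed edgeR's test in both comparisons. The 2514 green points share their direction, and r across all genes is 0.949.

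The comparison of the combination with the extract alone measured the antibiotic's effect in the presence of the extract. edgeR called 3 genes, all of them among the 7 neighbouring cit genes of citrate fermentation. The citrate lyase subunit gene citE (Ecoli_2532_03740) rose from 5.38 ± 0.36 to 38.3 ± 9.84 CPM (log2 2.83 ± 0.24, edgeR adjusted p = 5.96e-05), and citF from 56.9 to 163 CPM (1.51 ± 0.23, adjusted p = 0.0157). The remaining call, citD (2.31 ± 0.30, adjusted p = 0.00517), lies under the mean CPM of the naming rule and was chosen after its values were seen. Its levels were 1.74 and 8.76 CPM. Of the neighbouring genes, also chosen so, citC, citG, citT and citX were at 2.36, 1.79, 1.13 and 0.50 with edgeR adjusted p of 0.101, 0.14, 0.0598 and 0.995. All 7 had no overlap between the replicates of both groups.

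No panel gene passed (edgeR, adjusted p of 0.995 or more), with ampC_2 at -0.24, soxS at 0.01, ompF at 0.59, sulA at -0.41 and ftsI at 0.18. Camera called 2 lists and fry 0 of 32. The camera calls were the flagellar list (median 0.17, adjusted p = 0.0271; adjusted p = 0.895 with an estimated correlation) and the list for peptidoglycan synthesis and penicillin-binding proteins (median 0.09, adjusted p = 0.0271; adjusted p = 0.895 with an estimated correlation). None of their 47 and 34 members passed edgeR's test, over all genes or adjusted over the list alone. The flagellar call was lost without combination 1 (0.03, adjusted p = 0.258), combination 5 (0.24, 0.0628) or extract 5 (0.12, 0.436), and with library totals alone (0.27, 0.0694). The peptidoglycan call was lost without combination 1 (0.12, 0.282), combination 3 (0.11, 0.0533), extract 3 (0.08, 0.148) or extract 5 (0.10, 0.436), and its median was 0.15 without extract 1 and 0.16 with library totals alone. Of its members, murF, mreB and dacA were at 0.34, 0.29 and 0.30.

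DESeq2 called 11 genes and limma-voom 5. At an unadjusted p under 0.05 there were 186 genes, fewer than the share of 0.05 of the 4707 tested that chance alone would give. With 1 library left out this number ran from 110 (without combination 3) to 413 (without combination 5). The number of genes called by edgeR was 1 without extract 3 and 2 without extract 5. The call of citF was lost without extract 1, 3 or 5 (log2 1.49 to 1.54, adjusted p 0.0943 to 0.169) and that of citD without extract 3 (2.33, 0.055). For 78.5% of genes the 95% interval lay within 2-fold, and 306 genes (6.5%, against 10% by chance) had no overlap.

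**Figure D4:**
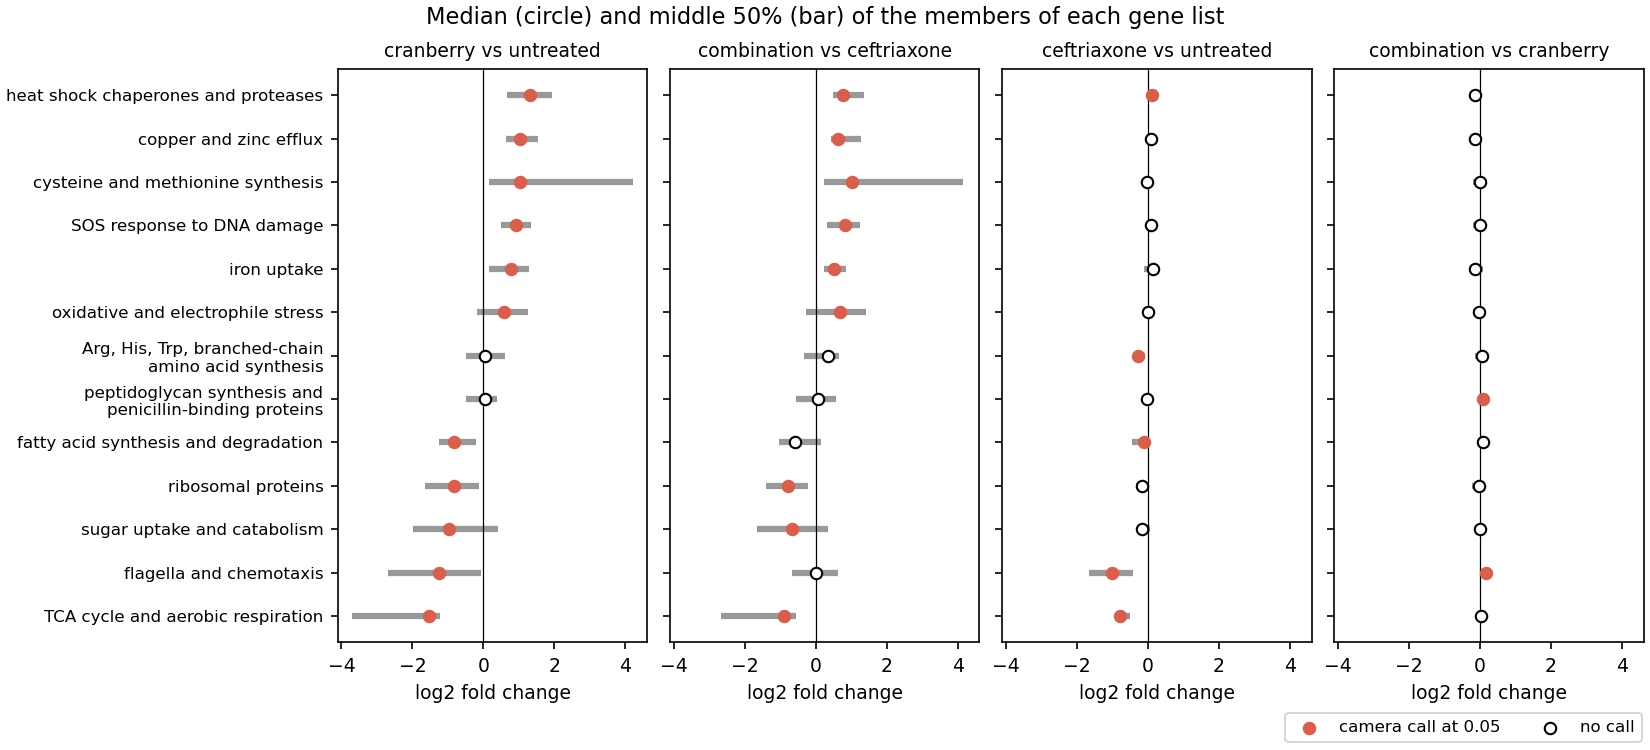
Median (circle) and middle 50% (bar) of the log2 fold changes of the members of 13 gene lists in 4 comparisons; filled circles are lists called by camera with its preset correlation. The lists for cysteine and methionine, heat shock, SOS and oxidative stress are called higher, and those for the TCA cycle, sugar uptake and ribosomal proteins lower, with the extract with or without ceftriaxone. No call holds with an estimated correlation (adjusted p of 0.227 or more). The flagellar and TCA medians under ceftriaxone alone are -0.27 and -0.34 without untreated replicate 1.

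The interaction asked whether ceftriaxone acted differently with the extract than without it. edgeR called 1 gene, citE: its change with ceftriaxone was larger in the presence of the extract by 2.33 ± 0.34 on the log2 scale (adjusted p = 0.0413). Without ceftriaxone its level was 2.54 CPM in untreated samples and 5.38 CPM with the extract, and with ceftriaxone it was 3.59 and 38.3 CPM. The flagellin gene fliC had an interaction of 2.18 (edgeR, adjusted p = 0.0838). Camera called 8 lists, led by the TCA list (median 0.72, adjusted p = 9.52e-15) and the flagellar list (1.23, adjusted p = 1.22e-14). All 8 had an adjusted p of 0.719 with an estimated correlation, and fry called none. When adjusted over the list alone, 5 TCA and 6 flagellar members passed. Without untreated replicate 1 the medians were 0.35 and 0.43. The call of citE was lost when any of 10 libraries was left out (log2 2.15 to 2.46, adjusted p 0.062 to 0.271), all but untreated 1 and combination 3. Without untreated 1, edgeR called 3 genes, and it called 0 in each of the fits without 1 of those 10 libraries. DESeq2 called 10 genes and limma-voom 0. At an unadjusted p under 0.05 there were 346 genes, where chance alone would give a share of 0.05 of the 4707 tested. This number was 204 without untreated 1 and 198 without ceftriaxone 5, each of 4726 tested and under that share. Without each of the other libraries it ran from 252 (without ceftriaxone 3) to 491 (without untreated 4).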

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

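All tests in this part of depth, length, single libraries and splits were chosen only after the results were seen, except the leave-one-out fits, the interaction test and the list tests. The results given here first are those where the interaction passed its test, that is, where the effect of ceftriaxone with the extract differed from its effect without it. For citE the difference was 2.33 on the log2 scale (edgeR, adjusted p = 0.0413), and this call was lost when any of 10 libraries was left out (adjusted p 0.062 to 0.271). Among the lists, camera called TCA cycle and aerobic respiration (median difference 0.72), flagella and chemotaxis (1.23), arginine, histidine, tryptophan and branched-chain amino acid synthesis (0.23), Cpx envelope stress (0.36), fatty acid synthesis and degradation (0.18) and purine and pyrimidine synthesis (0.15) upwards. It called heat shock (-0.28) and iron uptake (-0.22) downwards. All 8 had an adjusted p of 0.719 with an estimated correlation. Without untreated replicate 1, the TCA and flagellar medians were 0.35 and 0.43, and the other 6 calls were lost: amino acids 0.09 (camera, adjusted p = 0.118), Cpx 0.19 (0.127), fatty acids 0.11 (0.103), purines and pyrimidines 0.10 (0.127), heat shock -0.18 (0.0688) and iron uptake -0.14 (0.242). Other single libraries ended these 6 calls too: for amino acids untreated 3, extract 1 and 5, ceftriaxone 5 and combination 1 (adjusted p 0.0579 to 0.165), and for Cpx extract 1 (0.0503). For fatty acids they were extract 3 and 5, ceftriaxone 5 and combination 1 and 3 (0.0609 to 0.29), for purines and pyrimidines untreated 3, extract 5, ceftriaxone 5 and combination 1 (0.0667 to 0.368), and for heat shock extract 5 (0.119). For iron uptake they were extract 1, 3 and 5, ceftriaxone 1 and 5 and combination 1 and 3 (0.0507 to 0.168). Medians of calls that held moved to 0.36 without extract 3 for amino acids, 0.23 without combination 5 for Cpx and 0.30 without combination 5 for fatty acids. For purines and pyrimidines they moved to 0.24 without untreated 4, 0.23 without extract 3 or combination 3 and 0.26 without combination 5. For the count of genes called in the interaction, 19 of 100 splits gave as many, with 1 gene in the real split and 132 in the highest other, so chance is not excluded.

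The flagellar list was called lower with ceftriaxone alone (median -1.01; camera, adjusted p = 1.51e-16; adjusted p = 0.571 with an estimated correlation), with 1 of 47 members passing over all genes. An explanation by untreated replicate 1 went with the size: without that library the median was -0.27, while leaving out any other library gave -0.94 to -1.25. Untreated 1 alone did not account for fliC, which was -1.23 without it (edgeR, adjusted p = 0.0367), although that call was lost without any ceftriaxone library (adjusted p 0.241 to 0.381). Length bias and low depth of untreated 1 were argued against, since all genes of the same lengths deviated in it by 0.02 against 1.38 for the flagellar genes, and its total was 13.67 M, the largest of its group. Whether ceftriaxone has a smaller effect on flagellar genes stays open.

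Of the 7 cit genes, chosen after their values were seen, edgeR called citE, citF and citD higher in the combination than with the extract alone. The other 4 did not pass (adjusted p 0.0598 to 0.995), and the calls were lost for citF without extract 1, 3 or 5 (0.0943 to 0.169) and for citD without extract 3 (0.055). No single library carried the difference of citE: the smallest value with 1 library left out was 2.65 and the largest 3.02 (edgeR, adjusted p at most 0.00149). At equal depth citE was 2.92 (edgeR, adjusted p = 3.03e-05), so depth is argued against as the whole source of its difference. The split among extract-treated libraries described next gave the 7 genes a median of 0.36 against 1.70 for the real split, and citE 0.64 against 2.76. It holds combination libraries on both sides, and the genes were chosen after their difference between the groups was seen. A smaller value across that split was thus largely set in advance and cannot decide. For citE an effect of ceftriaxone in the presence of the extract may be a biological hypothesis, found and tested on the same data.

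A split of the extract-treated libraries that crossed their groups called 338 genes, many times the 3 of the real split, which points to a structure among these samples. Of the 10 splits of these libraries it called the most genes. It set extract 1, combination 1 and combination 3 against extract 3, extract 5 and combination 5. Both replicates 1 thus stood on 1 side and both replicates 5 on the other, with the replicates 3 divided. Whether the replicate number marks this structure was not tested. On the side of extract 1, 104 genes were higher and 234 lower. Depth was argued against, since that side held both the smallest total and the largest, 11.32 M. Length bias cannot be told apart: 99.6% of the median size of the called genes was left after the trend with length was removed, but 60.9% of them have a K-12 length, too few for the check, which is void. No biological explanation was tested.

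For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. Where the groups differ by the extract, every other split mixes libraries with and without it in a group. The extract's difference then counts as spread, so the 0 calls of those splits were largely set in advance and lend no support. The real split gave 3026 genes for extract and untreated (1 of 10 splits gave as many; highest other 0), 2 for ceftriaxone and untreated (1 of 10; 0), 2992 for combination and untreated (1 of 10; 0), 2813 for combination and ceftriaxone (1 of 10; 0) and 3 for combination and extract (2 of 10; 338).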

How the results depend on the processing

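The tests with a robust dispersion, library weights, thinning, numbered copies and without both untreated 1 and extract 1 were chosen after seeing the data. The counts of genes called for extract and untreated stayed within 1.5 times of 3026 in every alternative run (2034 with glmTreat to 3095 with library weights; 2786 to 2900 with 1 library left out). Those for combination and untreated (2992) and combination and ceftriaxone (2813) did so except with glmTreat (1943 and 1699), which tests against a 1.5-fold change; with 1 library left out they ran from 2688 to 2952 and from 2433 to 2764. For ceftriaxone and untreated (2 genes), the count was 0 with library totals, no filter, glmTreat, only the 6 libraries compared and thinning, 1 without both untreated 1 and extract 1, 5 with limma-voom, 48 with DESeq2 and 251 with library weights. With 1 library left out it ran from 0 (without any ceftriaxone library) to 52 (without untreated 4), and was 1 without untreated 1 or 3. For combination and extract (3 genes), it was 5 with limma-voom, only the 6 libraries compared and without both, and 11 with DESeq2; it ran from 1 (without extract 3) to 3, with 2 without extract 5. For the interaction (1 gene), it was 0 with limma-voom, no filter and glmTreat, 2 with library totals and without both, 6 with library weights and 10 with DESeq2, and ran from 0 to 3 (without untreated 1). For these 3 counts the cause was not tested. DESeq2 size factors, a mean of 50 or more counts and a robust dispersion kept all 6 counts within 1.5 times. Depth limits low values: 3 counts in the smallest library are 0.501 CPM, and thinned to 5.99 M the libraries gave 2861 genes for extract and untreated.

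The list calls in this paragraph and the next rest on camera's preset correlation. For combination and extract, the ribosomal list was not called with all libraries (median -0.03; adjusted p = 0.987 with an estimated correlation). It was called downwards at -0.205 without extract 1 (camera, adjusted p = 0.0131) and at -0.206 without both (0.00371), and upwards at 0.169 without extract 3 (0.00439). The TCA list there (0.02, not called) was called at 0.197 without extract 3 (0.0258) and was -0.101 without combination 1 (0.387). The ribosomal list in the interaction (0.135, not called) was called downwards at -0.211 without both (0.0172), and upwards at 0.357 without extract 3 (0.000741) and 0.21 without untreated 4 (0.0406). The cause was not tested. Over the comparisons, the fit without both untreated 1 and extract 1 ended 9 list calls and added 4 in the direction seen with all libraries. Numbered copies ended the list calls of flagella (0.0797) and peptidoglycan synthesis (0.0542) for combination and extract, and of copper and zinc efflux (0.0698) for combination and ceftriaxone. Library weights ended those of heat shock (0.02, adjusted p = 0.566) and fatty acids (0.0866) for ceftriaxone, flagella (0.123) for extract and untreated, fatty acids and iron uptake (0.0823 each) for combination and untreated, iron uptake (0.0613) for combination and ceftriaxone, and 4 in the interaction. No named gene changed direction where the main or the alternative fit called it. Values of named genes said here to have moved changed direction with no call in either fit. Of the values of named genes across alternatives, those that kept direction and side of the threshold, gained a call, lost one or moved were 2706, 5, 20 and 3 for extract and untreated, and 2325, 72, 19 and 49 for ceftriaxone and untreated. They were 2725, 7, 19 and 3 for combination and untreated, 2391, 3, 21 and 13 for combination and ceftriaxone, 2364, 14, 5 and 31 for combination and extract, and 3119, 14, 15 and 39 for the interaction.

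Whether the replicate numbers pair the samples is not stated in the labels, and the values do not settle it. Over 15 pairs with the same number, the correlation of deviations from group means ran from -0.36 to 0.28 (median 0.05, 5 over 0.1). For pairs with different numbers the median was -0.02, and 6 of 11 libraries correlated best with their own number. With the replicate number as a block, the counts were 2852 (extract and untreated), 18 (ceftriaxone and untreated), 2805 (combination and untreated), 2803 (combination and ceftriaxone), 4 (combination and extract) and 0 (interaction). Number 4 marks only untreated 4, so in this fit that library had a term of its own and did not inform the group means. Without untreated 4 and with no block, the count for ceftriaxone and untreated was 52. Where the untreated group enters, changes under the block can thus come from the loss of that library as well as from pairing. The block also ended 4 calls of lists by camera. For ceftriaxone and untreated these were fatty acids (median -0.174, adjusted p = 0.055) and heat shock (0.117, 0.055). For combination and extract they were flagella (0.172, 0.0581) and peptidoglycan synthesis (0.092, 0.0679). The block added 7 calls by camera, also with the preset correlation. For ceftriaxone and untreated they were Cpx, peptidoglycan remodelling and ribosomal proteins (adjusted p = 0.0498 each). For combination and untreated they were flagella (0.00873) and multidrug efflux (0.0421). In the interaction they were ribosomal proteins (0.242, adjusted p = 0.0378) and SOS (0.0426).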

Other observations

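The runs of neighbouring genes in this part were chosen after their values were seen, and no test of enrichment was made on them. In extract against untreated, the 20 genes from xdhA to uacT, in K-12 order, all fell, with a median log2 of -6.91 (-9.02 to -3.59). The run holds genes for purine catabolism and transport, among them xdhA to xdhD, guaD and xanQ, and the genes ygeW, ygeX, ygeY, ygfK and ssnA. In combination against ceftriaxone all 20 were also called by edgeR, with a median of -6.19.

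Other runs fell as well: the 10 genes from gltA to mngA, which include sdhC to sucD of the TCA cycle, had a median of -4.53 (-3.85 in combination against ceftriaxone). The 6 genes from ydjH to msrB had -4.45 (-3.61), the 5 cyo genes of cytochrome bo oxidase -4.46 (-2.86), the 4 genes from mglC to galS of galactose uptake -6.46 (-5.32) and the 4 nrf genes of nitrite reductase -3.34 (-3.10). The 5 genes from cysM to cysP rose, with a median of 7.29 (6.91). The 7 neighbouring cit genes rose with the extract alone too, from citT (0.867) and citE (1.077) to citG (3.127) and citX (3.206), all with an edgeR adjusted p of at most 0.00688.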
